A study of Equus caballus with 8 samples.

How the data were processed

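Poly(A)-selected RNA was fragmented with zinc ions, copied with random hexamers, size-selected and sequenced on an Illumina Genome Analyzer, per the labels' protocols. The deposited files hold single 35-base reads, 1 record each, that the authors named as unmapped. The aligner, the genome build and the rule by which a read was left unmapped are not given in the sources used here. Every quality line holds the same placeholder, so no read was filtered on base quality. Each file was tied to its sample by the sample identifier in the file name, since the file list names no sample, and each sample to its group by its title, tissue and treatment labels. The 8 groups have 1 library each, so no test across samples was made.

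The design fixed before the data were examined rested on alignment to annotated genes. No genome or annotation was given, so gene counts, the 27 gene lists, random-list percentiles, junction counts and the rule for named genes were not analysed here. The planned fallback, shares of read classes by sequence alone, was run: a run of at least 15 A or T, 14 matching adapter bases, at most 10 distinct words of 3 bases (low complexity), and bases called N. What follows was chosen after the files had been opened.

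A panel of 55 peptide sequences (13615 residues) was written from memory, with no database or file to check it against. Probe sequences for ribosomal RNA, adapter and phage control DNA were written in the same way. Several peptides follow the human protein, and their accuracy for the horse was not checked. The panel was written before any match was counted. All 6 reading frames of each read were translated, with the mitochondrial code for cytochrome c oxidase subunit 1, and a read was assigned to an entry when it held an exact 10-residue window of that entry alone. A window that a paralog outside the panel shares cannot be told apart. A mismatch between the recalled and the horse sequence removes reads, so a low count or 0 does not show absence: interleukin-1 beta and CXCL8 had 0 reads. Reversed sequences of the panel served as decoys and gave 2 reads against 2522240 for the 51 entries other than collagens, and 68933 against 3298354 for the 4 collagen chains, whose repeats also match when reversed. Decoys measure chance matches and not whether a recalled sequence is right. Entries are named in the LPS comparisons by the planned size rule, at least 2-fold with an interval excluding 1 and at least 50 reads over both libraries, with collagens, decorin, vimentin and, in synovium, serum amyloid A added after their values were seen. Tissue entries were also picked from the panel after their values were seen.

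Collagen-like reads had glycine at 4 positions spaced by 3 in the 11 residues of a frame, no stop codon and at least 2 prolines, and the decoy shuffled the codons of each read. Ribosomal RNA and phage matches needed a shared word of 24 bases. Library similarity used 25-base words kept at 1 in 64 by a hash, from reads without N, adapter, poly(A) run or low complexity. Reads of panel entries other than collagens and cytochrome c oxidase subunit 1, at most 20000 per entry and library, were compared base by base with the majority sequence of both cartilage libraries and cerebellum where 20 reads covered each base. Rates have exact Poisson 95% intervals, shares Clopper-Pearson intervals, and ratios the exact interval conditional on the sum of both counts. A count of 0 was set against a floor of 3 reads. The depth of 4198918 to 11866666 reads puts that floor between 0.253 and 0.714 RPM.

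The read assignment was tested on simulated data. For the 51 entries other than collagens, 97.6% of 64800 simulated reads returned to their entry, 0 went to another entry and 0 of 400000 random reads were assigned. Of 20 entries changed 4-fold between simulated libraries 20 were called, and 0 unchanged entries were. Each unchanged entry was given the same number of simulated reads in both libraries, so the 0 does not measure false calls between real libraries. The simulation drew on the panel itself, so it tests the code and not the recalled sequences. Alternatives were 9 and 11 residues, distinct sequences (relative to deposited reads for panel entries and to distinct sequences for collagen-like reads and read classes, each also run the other way for the LPS ratios), other read minimums, other proline minimums, totals without technical reads (those with N, adapter, poly(A) run or low complexity), decoy reads subtracted from collagen ratios, and scaling by the median ratio or by elongation factor 1-alpha. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and numba 0.67.0 were used.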

Results

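Messenger RNA of the horse was sequenced in 8 libraries from 6 tissues, with 1 library per group. Articular cartilage and synovium of a pony were each taken from a carpal joint given 4 injections of 0.5 ng lipopolysaccharide (LPS, a bacterial cell wall component that provokes inflammation) over 8 days and from the opposite carpal joint given phosphate-buffered saline (PBS). Placental villous tissue, testis, cerebellum and a whole embryo at 34 days of gestation came from thoroughbreds. The listed age was 3 years for the joint tissues, 4 years for testis and 2 years for cerebellum. The deposited files hold single reads of 35 bases that their names describe as unmapped, 71572856 in all. They numbered 10120028 in LPS cartilage, 8344166 in PBS cartilage, 4991553 in placental villous tissue, 4198918 in testis, 9314732 in cerebellum, 10901671 in embryo, 11866666 in PBS synovium and 11835122 in LPS synovium. Rates are reads per 1000000 of these reads (RPM). Total sequencing depth was not given in the sources used here, so no rate is an expression level. With 1 library per group no difference has a replicate check, and the 95% intervals cover counting error only, since PCR copies of a molecule were not marked. Proteins are named where the translated read held an exact stretch of 10 residues of a peptide sequence written from memory, without a database, so each name rests on that recalled sequence. Counts can be too low where the horse differs from it, and too high where a relative outside the panel shares the stretch or, for collagens, by chance matching.

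The tissues were told apart by reads of the proteins that characterise them. The title of the series concerns gene structures, and this comparison shows which panel entries the unmapped reads matched. Of 71572856 reads, 3298354 were assigned to the collagen chains and 2522240 to other entries. The rest were assigned to no entry, and their origin was not determined. Type II collagen alpha1, the main collagen chain of cartilage, gave 107605 RPM in LPS cartilage and 58903 in PBS cartilage, against 1407 in embryo and 3.33 in cerebellum. Type I collagen alpha1, the main chain of fibrous tissue, gave 45449 RPM in PBS synovium and 26897 in LPS synovium, and 3136 in placental villous tissue. Myelin basic protein, a component of the sheath of nerve fibres, gave 625 RPM (95% Poisson interval 609 to 641) in cerebellum and at most 0.801 in any other library. SNAP-25, part of the machinery of neurotransmitter release, gave 469 (455 to 483) in cerebellum and at most 4.86 elsewhere. The calcium-binding protein S100B gave 65.2 (60.1 to 70.6) in cerebellum and at most 1.56 elsewhere.

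The embryo library held 2782 RPM of haemoglobin alpha (2751 to 2813), 326 of haemoglobin beta (316 to 337) and 507 of serum albumin (494 to 521). Insulin-like growth factor 2, a fetal growth factor, gave 1459 RPM in placental villous tissue (1426 to 1493) and 594 in embryo (580 to 609). The alpha chain shared by the glycoprotein hormones gave 6.81 RPM in placental villous tissue (4.72 to 9.52) and at most 0.421 elsewhere. Transition protein 1, which replaces histones in maturing sperm, was seen in testis alone, with 21 reads or 5.001 RPM (3.10 to 7.65), of which 3 matched 11 residues. Of 18 panel entries with a tissue named beforehand, 16 had at least 20 reads and 15 of these ranked first in that tissue, the mean of both joint libraries standing for cartilage and for synovium. The exception was insulin-like growth factor 2, listed for the embryo. The tissues were named after the files had been opened and before any match was counted.

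**Figure D1:**
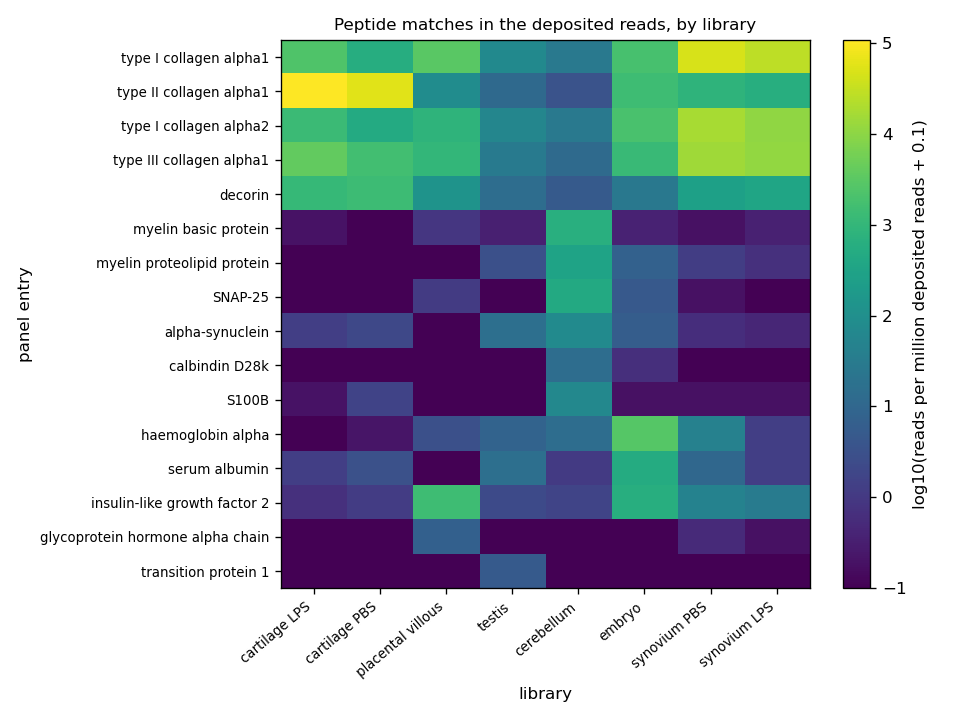
RPM for the 16 panel entries with a tissue named beforehand and at least 20 reads (rows) in the 8 libraries (columns), as log10 of the rate plus 0.1, with 1 library per column and no error shown. Type II collagen alpha1 was highest in the cartilage libraries at 107605 and 58903 RPM, and myelin basic protein in cerebellum at 625.

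A second set of proteins was far higher in both cartilage libraries and cerebellum than in the other 5 libraries. Elongation factor 1-alpha, which brings transfer RNAs to the ribosome, gave 15268 RPM in LPS cartilage, 22971 in PBS cartilage and 9286 in cerebellum, but 17.9 to 56.3 in the other 5 libraries. The lowest rate of the 3 libraries was at least 10 times the highest of the 5 for 6 of 48 entries, which were elongation factor 1-alpha, the ribosomal protein S27a tail, ferritin heavy chain, ubiquitin, beta-2 microglobulin and manganese superoxide dismutase. The gap was 165-fold for the first and 14.5-fold for the last. Against the majority base sequence of the 3 libraries, 87.03% to 92.3% of elongation factor 1-alpha reads in each of them had no mismatch, but 0 of 2047 in the other 5 libraries, where 63 had 2 mismatches and 1984 had at least 3. Of 30 entries with at least 20 such reads in each set, 7 had 0 reads without a mismatch in the 5 libraries, while vimentin had 83.2% there and 84.8% in the 3. Reads of 18S ribosomal RNA were 1.84% of the cerebellum library, 0.328% of LPS cartilage and 0.243% of PBS cartilage, and between 0.0271% and 0.0682% of the others. Rates of such entries are therefore compared below only between the LPS and PBS libraries of 1 tissue, apart from values listed under other observations.

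In cartilage the LPS library was set against the PBS library to see which transcripts differed after repeated exposure of the joint. Serum amyloid A, an acute-phase protein of inflammation, had 14383 reads in the LPS library and 79 in the PBS library, or 1421 (1398 to 1445) against 9.47 (7.50 to 11.8) RPM, a ratio of 150 (exact interval 120 to 190), or 16.7 over distinct sequences. Manganese superoxide dismutase, a mitochondrial antioxidant enzyme, was 2.48-fold higher (2.21 to 2.79) in the LPS library, at 116 against 46.7 RPM, but 1.39-fold over distinct sequences and 1.86-fold with the median of ratios. An entry recalled as the catalytic region of the matrix-degrading enzyme MMP-3 had 47 against 5 reads, a ratio of 7.75 (3.10 to 24.97), or 2.06 with 10 against 4 distinct sequences. Its reads began at only 3 residues of the stretch and 0 of 345 over all libraries matched 11 residues, so this name is uncertain. The 4 collagen chains of the panel were higher in the LPS library. Type I alpha1 was 4.26-fold higher (4.13 to 4.39), type I alpha2 2.76-fold (2.67 to 2.86), type III alpha1 2.34-fold (2.29 to 2.38) and type II alpha1 1.83-fold (1.82 to 1.83). For type I alpha1, reversed sequences matched 15.01% as many reads in the LPS library and 35.8% as many in the PBS library. Its ratio was 1.96 over distinct sequences, 3.39 with 9 residues, 4.57 with 11 and 5.64 with decoy reads subtracted. Over distinct sequences the ratio was 1.58 for type I alpha2, 1.49 for type III alpha1 and 1.31 for type II alpha1.

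Of 31 entries with at least 50 reads over both cartilage libraries, 10 were at least 2-fold higher in the LPS library with an interval that excluded 1 and 0 were as much lower. Besides those named, they were muscle actins at 4.24-fold (2.81 to 6.61), thymosin beta-4 at 3.67-fold (2.87 to 4.75), galectin-1 at 2.71-fold (2.02 to 3.68) and the mitochondrially encoded cytochrome c oxidase subunit 1 at 2.40-fold (2.37 to 2.43), the last 2 at 1.65-fold and 1.27-fold over distinct sequences. In PBS synovium muscle actins gave 192 RPM, thymosin beta-4 191, galectin-1 258 and type I alpha1 45449. In PBS cartilage they gave 3.36, 9.47, 7.19 and 564 RPM. Manganese superoxide dismutase is left out because of the gap described above. Synovial tissue in the LPS cartilage sample was therefore not excluded. Serum amyloid A gave 6.91 RPM in PBS synovium and 7.86 in LPS synovium, against 9.47 in PBS cartilage and 1421 in LPS cartilage. For that entry alone, these values argue against synovial tissue as the source of the difference. Vimentin, an intermediate filament of connective tissue cells, was lower in the LPS library at 1765 against 2664 RPM, a ratio of 0.663 (0.650 to 0.676), or 0.997 relative to elongation factor 1-alpha and 0.497 with the median of ratios. Decorin, a small proteoglycan that binds collagen, stood at 1117 against 1351 RPM, a ratio of 0.827 (0.806 to 0.849), which turned to 1.24 relative to elongation factor 1-alpha. The median ratio over the 31 entries was 1.33 and that of elongation factor 1-alpha was 0.665, so values close to these depend on the scaling. With each distinct read sequence counted once, relative to deposited reads as in the ratios above, 3 of the 10 still met the size, interval and 50-read criteria, which were serum amyloid A, muscle actins at 2.89 and thymosin beta-4 at 2.18. Relative to distinct sequences of the library 4 did, type I alpha1 being added at 2.33. With the median of ratios 7 did, without type III alpha1, manganese superoxide dismutase and cytochrome c oxidase subunit 1. Counting distinct sequences merges PCR copies and also separate molecules with the same read, so calls lost there do not show copies.

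In synovium collagens were lower in the LPS library. Type I alpha1 gave 26897 RPM in the LPS library and 45449 in the PBS library, a ratio of 0.592 (0.589 to 0.594). The ratio was 0.633 (0.628 to 0.637) for type I alpha2 and 0.746 (0.741 to 0.751) for type III alpha1. Blood proteins differed more. Haemoglobin alpha had 14 reads in the LPS library and 529 in the PBS library, 37.7-fold lower (22.3 to 69.4), a ratio of 0.0265, or 0.0442 over distinct sequences. Haemoglobin beta had 0 against 62, at least 20.6-fold lower against a floor of 3 reads per library, and serum albumin 14 against 123, 8.76-fold lower (5.03 to 16.5). These 3 were the entries at least 2-fold apart among 33 with at least 50 reads, and haemoglobin beta fell short of 50 over distinct sequences and with 11 residues. Haemoglobin alpha and serum albumin gave 44.6 and 10.4 RPM in PBS synovium, and were highest in embryo at 2782 and 507 RPM. The source of these reads in PBS synovium was not tested. Serum amyloid A stood at 7.86 against 6.91 RPM, a ratio of 1.14 (0.836 to 1.55), a difference not detectable at this depth. Decorin was 1.32-fold higher (1.26 to 1.38) in the LPS library.

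**Figure D2:**
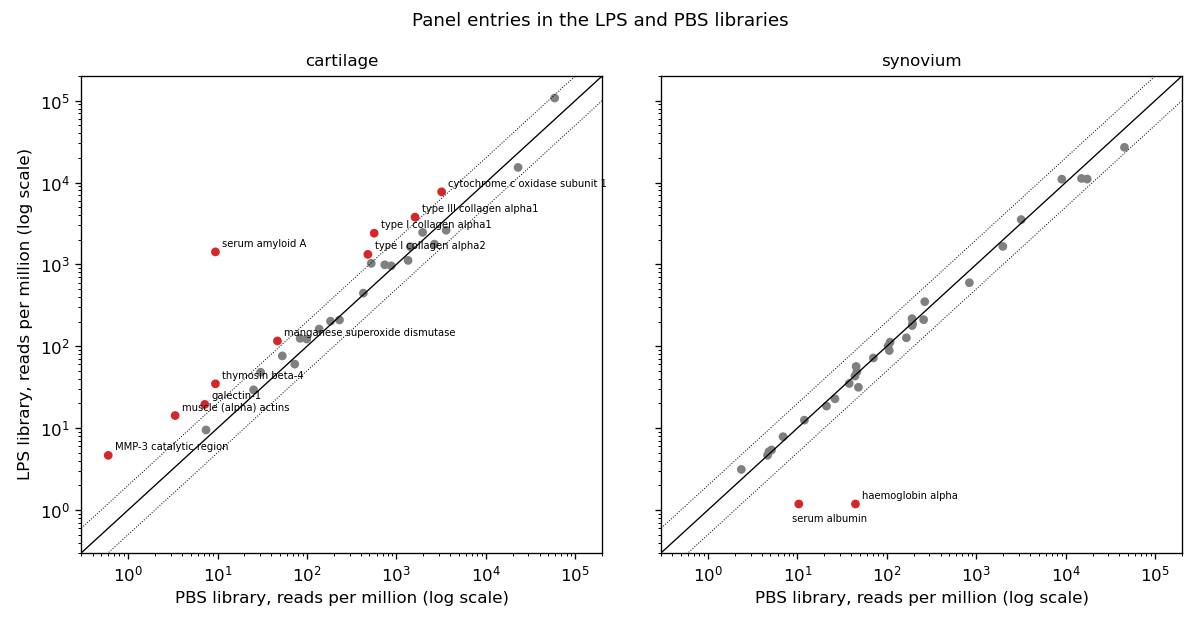
RPM in the LPS library against the PBS library (both log scales) for panel entries with at least 50 reads over both libraries, in cartilage (left) and synovium (right), each point being 1 entry without error bars. The solid line marks equal rates, dotted lines mark 2-fold, and red points are at least 2-fold apart with an interval that excludes 1. Serum amyloid A lies 150-fold above the line in cartilage (16.7-fold over distinct sequences), and haemoglobin beta, at 0 reads in the LPS library, is not drawn.

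The collagen signal did not depend on recalled sequences alone. Reads were also counted when all 11 translated residues followed the collagen pattern of a glycine followed by 2 other residues, repeated, with at least 2 prolines. Such collagen-like reads made up 82000 RPM of LPS cartilage (81823 to 82176; SD over 4 lanes of the library 715) and 44228 of PBS cartilage (44085 to 44371; SD over 4 lanes 758), a ratio of 1.85 (1.85 to 1.86). They made up 45499 RPM of LPS synovium (SD over 7 lanes 5334) and 69126 of PBS synovium (SD over 7 lanes 2211), a ratio of 0.658 (0.656 to 0.661). Lanes are repeat runs of 1 library, so their SD is technical. After shuffling the codons within each read the rates were 1562, 1007, 1047 and 1301 RPM in the same order. Cerebellum with 495 and testis with 661 RPM lay above their shuffled values of 334 and 472, by far less than the joint libraries did. Type II alpha1 was 93.5% (Clopper-Pearson interval 93.4 to 93.5) of the reads assigned to the 4 collagen chains in LPS cartilage and 95.7% (95.6 to 95.7) in PBS cartilage. In synovium it was 1.07% with PBS and 1.20% with LPS, but reversed sequences of the same chain matched 6934 and 4067 reads there against 9953 and 7067, so these shares lay close to chance matching.

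The LPS ratios of the joint tissues were set side by side to see whether the same proteins differed in both. Directions were counted relative to deposited reads over 27 entries with at least 50 reads in both, requiring both intervals to exclude 1. Of these entries, 3 were higher in the LPS library in both tissues and 0 were lower in both. Another 8 were higher in cartilage and lower in synovium, and 2 were the opposite. These counts depend on the setting. Among the 8, type II alpha1 lay close to chance matching in synovium, with a ratio of 0.9964 there after decoy reads were subtracted. Over distinct sequences relative to deposited reads, only the matrix protein osteonectin (0.9226) and alpha tubulins (0.9267) of the 8 fell below 1 in cartilage. The 2 were vimentin and decorin, and relative to elongation factor 1-alpha in cartilage they gave 0.9969 and 1.244. For the other 14 of the 27 entries the interval included 1 in at least 1 tissue. These include elongation factor 1-alpha, ubiquitin, heat shock cognate 70, HMGB1 and ferritin heavy chain, for which 0 synovium reads matched the majority sequence described above. Their synovium ratios therefore rest on other reads than most of those in cartilage, and they enter the correlation below. The Spearman correlation of the log2 ratios across entries was -0.17, and entries are not independent replicates. No library is shared by the ratios.

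Reads with a run of at least 15 A or T were 4.33% (4.32 to 4.34) of the embryo library, 1.90% of LPS synovium and 0.817% of PBS synovium, and 0.0541% to 0.193% of the other 5. Lanes of the embryo library ranged from 1.12% to 6.75%. Over distinct sequences the shares of embryo, LPS synovium and PBS synovium were 0.0610%, 0.0630% and 0.02999%, and both cartilage libraries, at 0.0789% and 0.0796%, lay above the embryo. Adapter sequence was found in 0.0604% to 0.175% of reads with 14 matching bases and in 0.2996% to 1.87% with 12, and a base called N in 0.306% to 1.88%. By the abundance of sampled 25-base words, the cartilage libraries shared 58.2% and the synovium libraries 52.9%, the highest values among the 28 pairs, and the next pair, embryo and LPS synovium, shared 32.1%.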

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

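The tests of the collagen ratios were set after the files had been opened and before the counts were seen, apart from the settings named below as added, and the share of type II in the gain was computed after. Collagen-like reads differed in opposite directions between the joint tissues, with an LPS to PBS ratio of 1.85 in cartilage and 0.658 in synovium. The difference between tissues was not tested, since each ratio rests on 1 library per condition. Leaving technical reads out of the totals gave 1.83 in cartilage and 0.667 in synovium. At least 97.14% of the reads were kept in each joint library, so this setting could not have moved either ratio far. Technical reads were thus too few to be the whole cause. Counting distinct sequences gave 1.70 and 0.703, which argues against a few sequences in many copies as the whole cause. Relative to deposited reads, a setting added after, distinct sequences gave 1.43 and 0.741. Type II alpha1 in cartilage went from 1.83 to 1.31, against 1.55 relative to distinct sequences. Distinct counts also merge reads of different molecules with the same sequence, so the part due to copies cannot be told. Another tissue in one of the samples was tested by the ratio of type I alpha1 over that of type II alpha1, 2.33 in cartilage and 0.831 in synovium, or 1.5 to 3.09 and 0.595 to 1.08 under settings added after. In cartilage the value of 2.33 passed the bound of 1.5 set beforehand for another tissue, with intervals that did not overlap. Type II alpha1 carried 90.95% of the rate gained over the 4 chains. That share alone cannot decide, since this chain was 93.5% and 95.7% of their reads in the LPS and PBS cartilage libraries. Type II alpha1 gave 597 RPM in LPS synovium and 839 in PBS synovium, against 107605 in LPS cartilage and 58903 in PBS cartilage. These values argue against added synovial tissue as the source of the type II gain. In synovium type II reads lay close to chance matching. A response to LPS and other differences in the tissue taken therefore both stay open.

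Reads that match phage control DNA lay outside every comparison. They came to 30.6 RPM in LPS cartilage, 23.1 in PBS cartilage, 22.0 in embryo, 27.98 in PBS synovium and 20.03 in LPS synovium, against 0.801 in placental villous tissue and 0.429 in cerebellum. Testis had 3 reads, no more than the floor. Lanes ranged from 0.000236% to 0.0116% of reads in LPS cartilage and from 0.000325% to 0.00839% in PBS cartilage, with an SD over lanes above the share of the whole library in both.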

How the results depend on the processing

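Alternatives other than those for poly(A), adapter and low-complexity reads were chosen after seeing the data, though collagen-like reads without technical reads and over distinct sequences were set before any count was seen. For the embryo, poly(A) reads were 4.42% with a run of 12, 4.28% with 20, 4.37% without reads holding an N and 0.0610% over distinct sequences; identical reads were merged there by construction. Adapter reads depended on the number of matching bases: with 12 instead of 14 they went from 0.0870% to 1.61% in embryo and from 0.102% to 0.2996% in LPS cartilage, which reordered the libraries. The collagen-like ratio kept its direction under each alternative run: in cartilage 1.84 with at least 1 proline, 1.85 with 3, 1.70 over distinct sequences (1.43 relative to deposited reads), 1.83 without technical reads and 2.79 relative to elongation factor 1-alpha; in synovium 0.663, 0.703 (0.741), 0.667 and 0.622 for 1 proline, distinct sequences, technical reads and elongation factor, whose synovium reads all had at least 2 mismatches. Entries at least 2-fold higher in LPS cartilage that also met the interval and 50-read criteria numbered 3 over distinct sequences relative to deposited reads, 4 relative to distinct sequences and 16 relative to elongation factor 1-alpha, instead of 10. Entries as much lower numbered 2 with a minimum of 10 reads and 2 with the median of ratios, instead of 0. The call of the entry recalled as MMP-3 was lost over distinct sequences, with 11 residues and with a minimum of 200 reads. In synovium 2 were higher with a minimum of 10 reads instead of 0, and 1 was lower with a minimum of 200 instead of 3. Decorin in cartilage reversed to 1.24 relative to elongation factor 1-alpha; the cause was not tested. The type II share over distinct sequences, 9 residues and 11 residues was 81.5%, 92.6% and 94.0% in LPS cartilage, 85.0%, 94.8% and 96.2% in PBS cartilage, 1.84%, 1.41% and 0.605% in PBS synovium, and 1.66%, 1.60% and 0.676% in LPS synovium. Apart from the merging of identical reads, the causes of these shifts were not tested. Not run were the base-quality, alignment-mismatch, transcript-part, multi-gene, junction and gene-list alternatives, for want of qualities or a reference. Depth limits entries near 3 reads per library.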

Other observations

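Alpha tubulins, the building blocks of microtubules, gave 8215 RPM in cerebellum (8157 to 8274), 1645 in LPS cartilage and 451 in embryo. Calmodulin, a calcium sensor, was highest in testis at 1515 RPM (1478 to 1553), followed by cerebellum at 618 (602 to 634). Muscle actins gave 617 (596 to 639) in placental villous tissue and 226 (217 to 235) in embryo, and myoglobin, the oxygen store of muscle, 8.26 (6.64 to 10.2) in embryo. Cytochrome c oxidase subunit 1 ranged from 3206 RPM in PBS cartilage to 60308 in cerebellum. These rates compare libraries across the gap in elongation factor 1-alpha described in the report, so they are values of the deposited reads only.

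The lag test below was set before its result was seen, and its split by chain after. Many exons of fibrillar collagen genes are known to be multiples of 54 bases long, so reads crossing junctions between short exons may be over-represented among unmapped reads. Read starts along the 4 collagen chains, over all libraries, had a mean autocorrelation of 0.121 at a lag of 54 bases, against at most 0.0378 at lags from 30 to 80 bases lying more than 9 bases away. Type I alpha1 at 0.181, type I alpha2 at 0.138 and type III alpha1 at 0.167 carried this mean, with their highest values at lags of 53 or 54. Type II alpha1, the chain with the most reads, had no such peak, with -0.00115 at 54 bases and 0.0369 at 30. The value of type II lay above its median of -0.0103, so the hypothesis stays open for all 4 chains, since repeats in the protein sequence were not excluded and no junction was placed without a genome.

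For the gap in elongation factor 1-alpha, the tests of start positions and of mismatch position were set after the gap and before their own results were seen, and the tests of mismatch counts and copy numbers after. Start positions were compared in 7 libraries, since testis lay below the minimum of 200 reads. They left higher expression with the same selection of reads undecided, with a median Spearman correlation of 0.301 between the 3 libraries and the others against 0.582 and 0.597 within the sets, short of the bound of 0.3 for the drop. Mismatches argue against it, since 0% of the elongation factor reads in each of the other 5 libraries matched the majority sequence, against at least 87.03% in the 3, and this factor is known to be needed in every growing cell. A related sequence may give reads of the 5 libraries, and mismatches on the first 5 over the last 5 sequenced bases, 1.42 over these libraries but 0.582 to 4.45 in single ones, left that open. Reads matching several places in the genome may have been kept in the 3 libraries only, but the copy numbers of the 6 entries with the gap are not known without a genome.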
